A study of Mus musculus with 6 samples.

How the data were processed

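The series holds 6 mouse spleen samples, 3 from mice overexpressing AIMP2-DX2 and 3 from control littermates, each on 1 Affymetrix array hybridised with biotin-labelled RNA that had been extracted with Trizol, per the labels. The values used were the log2 expression values that the authors deposited as 1 table for the whole series. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes arrays to one another and summarises the probes of a probe set. The version, the software and the annotation used are not given in the sources used here. That the scale is log2 was inferred from the range of the deposited values (0.771 to 13.3). RMA compresses large differences, so folds computed from these values can understate them, and normalization between arrays assumes that most transcripts do not shift together. The deposited values were kept as they are, and arrays carry no read depth, so their number limits the precision.

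The table held 41345 probe sets without missing values. By the platform annotation supplied with the series, 23521 probe sets had 1 gene symbol, 1814 had several and 16010 were unnamed, and no gene was named from a probe set with several. Of the 23521, 23328 were found by Entrez number in a table of mouse genes (assembly GRCm38.p6), and 0 symbols needed updating. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the gene table served for names and for gene order only. Each of 22180 genes was represented by the probe set with the highest mean over all 6 arrays, which mattered for the 1082 genes with more than 1. Array medians over all probe sets were 5.20, 5.17 and 5.16 in control and 5.12, 5.07 and 5.06 in DX2, a gap carried by the unnamed probe sets (median difference -0.10) and not by those with 1 gene (0.01). Pearson correlations across genes were 0.986 to 0.988 between control arrays, 0.967 to 0.983 between DX2 arrays and 0.963 to 0.981 between groups, genes not being independent replicates.

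Groups and replicate numbers were taken from the sample titles. Differences are DX2 minus control, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults, no covariate, no filter on dim probe sets), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The median standard error of a difference was 0.14. Data were simulated with means and spreads modelled on the real genes (22180 genes, 20 simulations of this comparison). In them 67.0% of genes changed by 1 on the log2 scale and 96.2% of those changed by 2 were called. Of the calls, 4.85% were unchanged genes. A simulated spread need not match that of the real gene or array, so these rates may differ in the real data. In those simulations, which draw genes independently and so cannot show the effect of correlation between genes, camera called a shifted B cell list in 20 of 20 and made 1 false call in 820 list tests.

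Before the data were examined, 44 gene lists were fixed, covering AIMP2 and its partners, signalling and stress responses, spleen cell types, neighbouring tissues and signs of handling. The sex-linked list was described per array, and the 43 others, each with at least 5 measured members, were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry's directional test were run beside it. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. List scores are means of log2 values and are not cell shares. The lists share members in places, such as Cr2, Dusp1 and Vcam1.

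The rule for named genes, also fixed before the data were examined, took for each direction the 12 genes with the largest absolute log2 difference among those that passed and whose 3 DX2 values all lay on one side of the 3 control values. Where fewer than 12 passed, it was filled with the non-overlapping genes of smallest unadjusted p with a log2 difference of at least 0.5, reported as not passing. Predicted symbols were counted and not named, and each list described could contribute up to 4 members of smallest unadjusted p. In this text a gene "rose" or "fell" only if it passed over all genes.

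The alternatives fixed beforehand were the replicate number as a block, each array left out in turn, a filter removing the 40% dimmest genes, a mean-variance trend, a robust prior, array weights, a second quantile normalization, centring each array on its median, the mean or the most variable probe set per gene, tests of every one-gene probe set, an added log2 size threshold of 1, an adjusted p under 0.1, and the other list tests. Chosen after seeing the data were a sex term, the 4 male spleens alone (1 control against 3 DX2, the lone control being assumed to vary like the DX2 spleens), and a test of all probe sets together. Both female spleens were controls, so the sex term and the male spleens give the same difference by construction, DX2 minus control 3. Equal values in these fits are therefore not separate evidence. An array was typed male where the mean of Eif2s3y, Kdm5d and Uty exceeded Xist.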

Results

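Gene expression was measured in the spleens of 1-year-old mice that overexpressed AIMP2-DX2 and of control littermates, with 1 Affymetrix array per sample and 3 arrays per group. AIMP2 is a scaffold protein of the multi-tRNA synthetase complex, and DX2 is a shortened splice form of it. Per the labels, the DX2 mice carried the doxycycline-dependent activator rtTA under the CAG promoter together with a responsive DX2 transgene, and the control mice carried the responsive transgene without the activator. Both groups ate doxycycline pellets (6.25 mg per kg) from the age of 8 weeks. The labels call the samples of each group biological replicates, and the comparison addresses which spleen transcripts differed between the groups. Since only the DX2 mice carried rtTA, an effect of DX2 cannot be told apart from one of rtTA. The median log2 value over 22180 genes lay between 5.42 and 5.46 on every array, and the number of arrays limits the precision of every value below.

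The groups differed in sex-linked transcripts, which the labels do not mention. Xist, the RNA expressed from the inactive X chromosome, stood at 10.9 in control 1 and 10.5 in control 2, against 3.89 in control 3 and between 4.02 and 4.29 in the DX2 arrays. The Y-linked Eif2s3y was low in control 1 (3.21) and control 2 (3.40) and high in control 3 (8.52) and the DX2 arrays (8.00 to 8.34), and Kdm5d and Uty followed the same split. By these transcripts 2 of the 3 control spleens were female and the 4 other spleens were male, so sex and genotype overlapped in part.

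**Figure D1:**
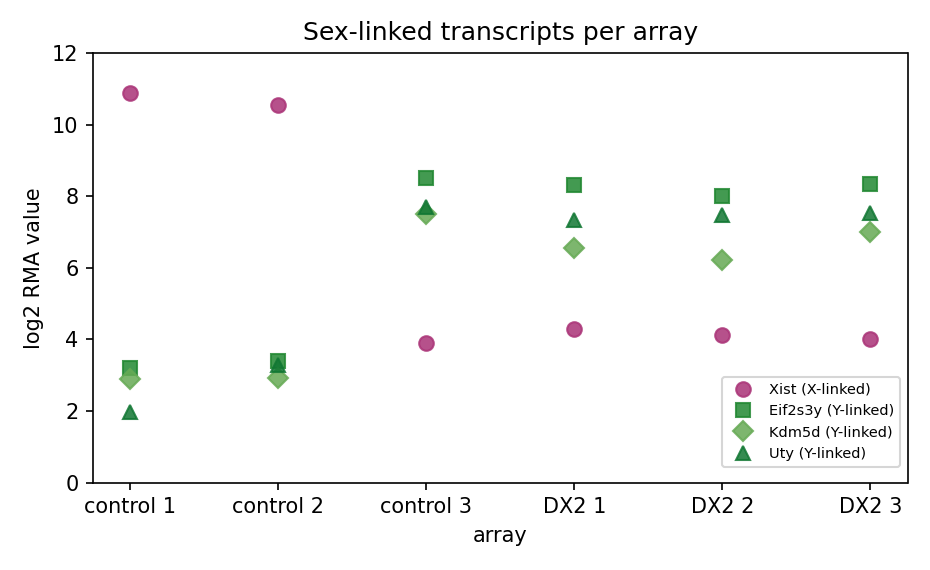
Log2 value (vertical axis) of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (horizontal axis); each point is 1 array. Xist was at 10.9 and 10.5 in controls 1 and 2 and at 4.29 or lower on the 4 other arrays.

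The induced gene itself gave no check of the group labels. The probe set that covers Aimp2 is annotated to Eif2ak1 as well, so its signal cannot be assigned to Aimp2, and whether it lies in the part that DX2 keeps is not given in the sources used here. It read 6.16 ± 0.16 in control and 6.42 ± 0.16 in DX2 spleens (log2, SD, n = 3 each). The difference of 0.25 (SE 0.13) did not pass limma's test (adjusted p = 0.410).

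DX2 spleens had far less transcript of B cell surface receptors and more of Gdpd3 than control spleens. Gdpd3, a lysophospholipase D of the glycerophosphodiester phosphodiesterase family, was 8.57-fold higher, at 7.99 ± 0.13 against 4.89 ± 0.08 (log2, SD, n = 3 each). Cr2, the complement receptor of mature B cells, was 8.95-fold lower, at 7.36 ± 0.91 against 10.52 ± 0.39, and Fcer2a, the low-affinity IgE receptor CD23, was 5.22-fold lower, at 6.83 ± 0.65 against 9.21 ± 0.42. In all, 70 of 22180 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 8 of them higher and 62 lower in DX2, and 12 of the 70 carried predicted or unnamed symbols. At an unadjusted p under 0.05 there were 3538 genes, 1804 higher and 1734 lower, and the groups did not overlap for 4874 genes, which is 22.0% against 10% by chance.

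The other genes that rose were smaller in size than Gdpd3. Cd5l, a protein secreted by tissue macrophages, rose by 1.35 (SE 0.18) on the log2 scale and Cd59a, an inhibitor of complement lysis, by 1.31 (SE 0.16). Ckap2l (1.12) and Racgap1 (0.79), which act at the mitotic spindle and in cytokinesis, also rose, as did the RNA-binding Lsm2 (0.95), Cln6 (0.88), a membrane protein of the endoplasmic reticulum, and the kallikrein Klk1b11 (0.69), which belongs to a family of near-identical copies. Their adjusted p lay between 0.0387 and 0.0456, against 0.000208 for Gdpd3. Sap30 (0.82), Mgat4b (0.88), Tnfrsf21 (0.80) and Adamts5 (0.81) were higher in all 3 DX2 arrays without passing, at adjusted p of 0.0569, 0.0570, 0.0570 and 0.0577.

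The named genes that fell include B cell transcription and chemokine receptor genes. Ebf1, a transcription factor that sets B cell identity, fell by 1.84 (SE 0.24) on the log2 scale, the chemokine receptors Ccr6 by 1.61 (SE 0.20) and Cxcr5 by 1.54 (SE 0.22), and Icosl, the ligand of ICOS on antigen-presenting cells, by 1.38 (SE 0.13). The interferon-inducible Ifi214 fell by 1.91, but the Ifi200 family has near-identical copies, so its probe set is uncertain. Crisp3 fell by 1.80, Ralgps2 by 1.51, Phxr4 by 1.56 and the small nucleolar RNA Snora44 by 1.45. In DX2 spleens Crisp3 read 2.90 ± 0.32 and Ifi214 4.02 ± 0.41 (log2, SD, n = 3 each), and since the floor of detection is unknown the sizes of these 2 falls are uncertain. Ptcd3, a mitochondrial translation protein, fell by 1.31 on the probe set used, while its other probe set differed by -0.16, so the gene's change is uncertain. The adjusted p of these genes lay between 0.0329 and 0.0456, with 0.0431 for Cr2 and 0.0491 for Fcer2a (limma, Benjamini-Hochberg).

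**Figure D2:**
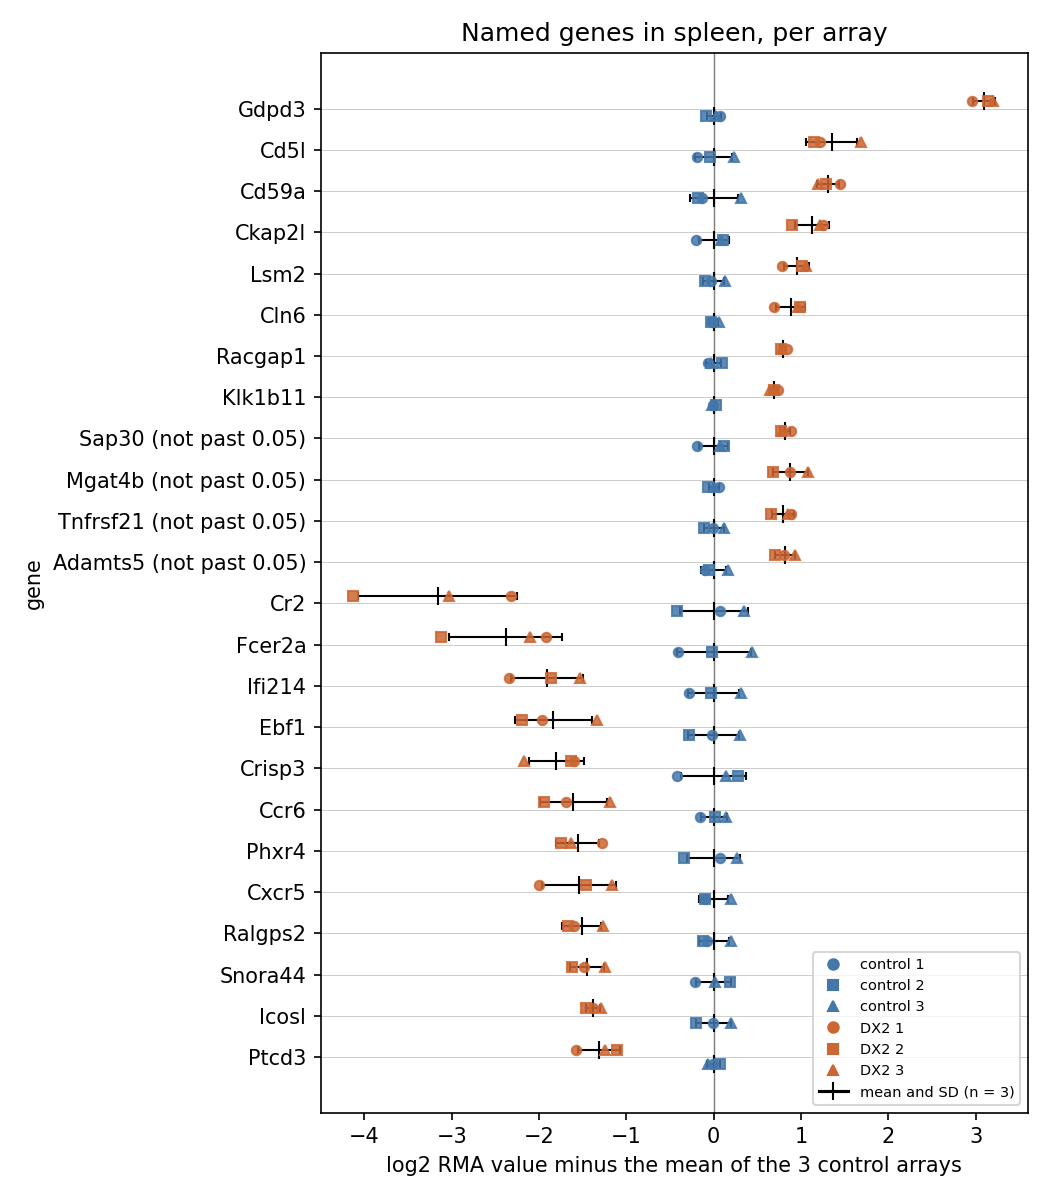
Log2 value of each named gene on each array minus the mean of the 3 control arrays (horizontal axis) for 24 genes (vertical axis); points are arrays, vertical marks are group means and bars are the SD (n = 3). In every gene the 3 DX2 arrays lie on one side of the 3 control arrays, as the rule that picked the genes required. The genes range from Gdpd3 (mean difference 3.10) to Cr2 (mean difference -3.16).

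At most 6 of the 70 calls held when an array other than DX2 2 was left out or a sex term was added, fits with fewer arrays or degrees of freedom, and all 70 held without DX2 2. Without 1 array the count was 1 (control 1, control 2 or DX2 3), 5 (control 3), 8 (DX2 1) or 372 (DX2 2), and with a sex term in the fit it was 2. The median absolute difference of the 70 genes was 1.10 in all spleens. It was 1.18 both with the sex term and among the 4 male spleens, 1 control against 3 DX2, which give the same difference by construction. Centring each array on its median over all probe sets shifted the median of all genes from 0.01 to 0.10 and left 2 calls. A second quantile normalization gave 20 higher and 64 lower, against 8 and 62. All 70 genes kept their direction under each of these settings, but they were picked on the same arrays, so this is not independent support.

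Among the gene lists fixed before the data were examined, the B cell list fell furthest. All 13 measured members were lower in DX2, with a median difference of -1.21, and 4 of them (Cr2, Cd79b, Cxcr5 and Fcer2a) passed over all genes, against 11 of 13 adjusted over the list alone. Cd79b, the signalling chain of the B cell receptor, fell by 1.14 (SE 0.16). The list passed camera with a preset correlation (adjusted p = 6.3e-12) and not with an estimated one (adjusted p = 0.377 with an estimated correlation). In the 4 male spleens its median was -1.30, and the list still passed with the preset correlation. Of 9 marginal zone B cell transcripts, 8 were lower (median -0.29, mean -0.71), with Cr2 the only one past the threshold, over all genes and adjusted over the list alone. That list passed too (adjusted p = 0.00406, and adjusted p = 0.377 with an estimated correlation), and its median was -0.44 without DX2 3 and -0.63 in the 4 male spleens.

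Antigen presentation and T cell transcripts were lower as lists, with wide spread among the DX2 spleens. All 9 MHC class II transcripts were lower (median -0.73), none past the threshold over all genes and 2 adjusted over the list alone, H2-Ob (-1.13, SE 0.22) and H2-DMb1 (-1.02, SE 0.21). The list passed with the preset correlation (adjusted p = 0.000751), but adjusted p = 0.534 with an estimated correlation, and without DX2 1 its median was -0.34 and it still passed. All 16 T cell transcripts were lower (median -0.38), with none past the threshold over all genes or adjusted over the list alone. The T cell list passed (adjusted p = 0.00415, but adjusted p = 0.585 with an estimated correlation), and its median was -0.61 without DX2 2 and 0.01 without DX2 1, where the call was lost. The list's mean log2 value was 6.59 in DX2 1, 7.89 in DX2 2 and 7.63 in DX2 3, against 7.59 to 7.89 in control spleens.

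Red pulp macrophage transcripts were higher with little spread. Of 18 measured members 16 were higher (median 0.48), 1 of them, Cd5l, past the threshold over all genes and 10 adjusted over the list alone. The complement genes C1qb (1.34, SE 0.25) and C1qc (1.13, SE 0.21) and the adhesion molecule Vcam1 (0.49, SE 0.13) were among the 10. The mean log2 value of the list was 9.14 ± 0.09 in DX2 and 8.55 ± 0.07 in control spleens (SD, n = 3 each). The list passed camera with the preset correlation (adjusted p = 1.7e-06) and had an adjusted p = 0.377 with an estimated correlation.

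Erythroid transcripts were higher in DX2 as a list and varied widely between spleens. All 26 measured members were higher (median 1.12), none past the threshold over all genes or adjusted over the list alone, with the erythroid transcription factor Klf1 at 1.83 (SE 0.71) and the haem synthesis gene Uros at 1.04 (SE 0.37). The mean log2 value of the list was 9.51 in DX2 1 and 9.17 in DX2 3 but 7.37 in DX2 2, against 6.55, 8.11 and 7.99 in controls 1, 2 and 3. The list passed (adjusted p = 9.98e-07), with adjusted p = 0.539 with an estimated correlation. Its median was 0.64 without control 1, 0.70 without DX2 1, 1.71 without DX2 2 and 0.73 in the 4 male spleens, and it passed in each. The neutrophil list (median 0.46) and the megakaryocyte and platelet list (median 0.49) passed at adjusted p of 0.0131 and 0.0157, with adjusted p = 0.664 and 0.661 with an estimated correlation and no member past the threshold over all genes or adjusted over the list alone. Both rested on DX2 1, where their scores were 8.69 and 8.61 against at most 7.57 and 7.07 on any other array, and without it their medians were -0.04 and -0.12. Both calls were also lost without control 1 (0.29 and 0.38), and the neutrophil call without control 2 (0.39). The neutrophil median was 0.73, 0.80 and 0.83 without control 3, DX2 2 and DX2 3, and the megakaryocyte median 0.94 without DX2 2.

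**Figure D3:**
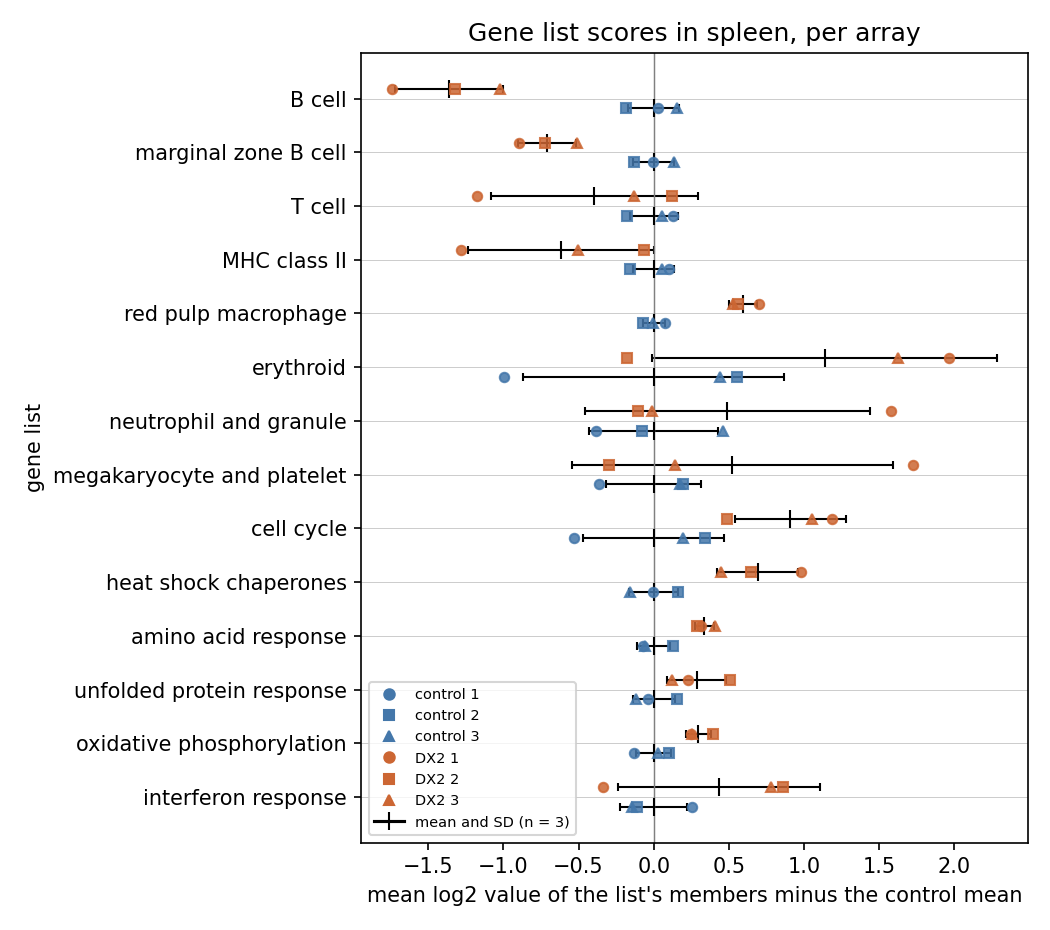
Mean log2 value of the members of 14 gene lists on each array minus the control mean (horizontal axis, log2; lists on the vertical axis); points are arrays, vertical marks are group means and bars are the SD (n = 3). The B cell list lies below the controls on all 3 DX2 arrays and the red pulp macrophage list above them, while the erythroid list of DX2 2 (7.37 before subtraction) lies within the control range of 6.55 to 8.11.

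Cell cycle transcripts were higher throughout. All 36 measured members were higher (median 0.94, 1.92-fold), with none past the threshold over all genes and 34 adjusted over the list alone. E2f1, a transcription factor of S phase entry, differed by 0.62 (SE 0.11), the mitotic kinases Aurkb and Plk1 by 1.06 (SE 0.20) and 1.10 (SE 0.23), and the kinesin Kif20a by 0.92 (SE 0.18). The list passed (adjusted p = 2.02e-19), with adjusted p = 0.493 with an estimated correlation. Its score was highest in DX2 1 and DX2 3 (8.57 and 8.44), the spleens with the highest erythroid scores, and was 7.87 in DX2 2 against 6.85 to 7.73 in control spleens.

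Stress and amino acid response lists were also higher. All 13 heat shock chaperones were higher (median 0.60), 0 over all genes and 10 adjusted over the list alone, including Hsph1 (1.07, SE 0.18), Hspa4l (0.80, SE 0.18) and Dnajb1 (0.60, SE 0.14), and the list passed (adjusted p = 9.56e-09, and adjusted p = 0.377 with an estimated correlation). Of 18 amino acid response genes 14 were higher (median 0.30), 0 past over all genes and 3 adjusted over the list alone, namely Shmt2 (0.59), Psat1 (0.55) and Mthfd2 (0.77), enzymes of serine and one-carbon metabolism (adjusted p = 0.000327 for the list, and adjusted p = 0.377 with an estimated correlation). All 14 unfolded protein response genes were higher (median 0.24, none past over all genes or adjusted over the list alone), led by Sdf2l1 (0.77, SE 0.19), at adjusted p = 0.000611 for the list and adjusted p = 0.534 with an estimated correlation. Their median was 0.15 without DX2 2, 0.15 with array weights and 0.41 in the 4 male spleens, and the list passed in each.

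The tRNA synthetases were slightly higher as lists, both those of the complex that AIMP2 scaffolds and the others. Of 9 members of the multi-tRNA synthetase complex 8 were higher (median 0.20), 0 past over all genes and 1 adjusted over the list alone, Eef1e1 (0.73, SE 0.15), which encodes the complex protein AIMP3. That list passed at adjusted p = 0.0108, with adjusted p = 0.534 with an estimated correlation, and the call was lost without control 1 (median 0.08). Of 11 other tRNA synthetases 10 were higher (median 0.28), with none past over all genes or adjusted over the list alone, and Gars differed by 0.42 (SE 0.11). Their list passed at adjusted p = 0.00435, with adjusted p = 0.493 with an estimated correlation. The median was larger outside the complex (0.28 against 0.20), so the shift was not particular to the complex of AIMP2. MYC targets, a list of growth and ribosome assembly genes, had a median of 0.22 and no member past over all genes or adjusted over the list alone, with Srm at 0.58 (SE 0.16) and Nop56 at -1.24 (SE 0.31). The list passed at adjusted p = 0.0048, with adjusted p = 0.493 with an estimated correlation.

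Energy metabolism and immediate response lists followed the same direction. All 27 oxidative phosphorylation genes were higher (median 0.29), 0 past over all genes and 5 adjusted over the list alone, among them Ndufb9 (0.68, SE 0.13) and Atp5b (0.46, SE 0.10), and the list passed at adjusted p = 9.77e-09, with adjusted p = 0.493 with an estimated correlation. Glycolysis genes had a median of 0.36, with none past over all genes or adjusted over the list alone, at adjusted p = 0.0083 and adjusted p = 0.535 with an estimated correlation, and the call was lost without DX2 2 (median 0.12). Immediate early genes had a median of 0.35 (0.23 with array weights, where the list still passed), with 0 over all genes and 4 adjusted over the list alone, Dusp1 (0.94, SE 0.14), Jun, Fosb and Fosl2, at adjusted p = 0.00265 and adjusted p = 0.377 with an estimated correlation. Glucocorticoid response genes, which include Dusp1, had a median of 0.48, with 0 over all genes and 2 adjusted over the list alone, at adjusted p = 0.0048 and adjusted p = 0.493 with an estimated correlation. The lists fixed beforehand included signs of handling, and whether unequal handling contributed to these shifts was not tested.

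Interferon response genes were higher in DX2 2 and DX2 3 and not in DX2 1. Of 25 measured members 21 were higher (median 0.47), 0 past over all genes and 2 adjusted over the list alone, Isg15 (2.83-fold) and Ifih1 (1.69-fold). The list score was 6.58 in DX2 1, 7.79 in DX2 2 and 7.70 in DX2 3, against 6.78 to 7.18 in control spleens. The list passed at adjusted p = 0.00731, with adjusted p = 0.606 with an estimated correlation, and the call was lost without DX2 2 (median 0.07) or DX2 3 (median 0.31) and kept without DX2 1 (median 0.84). It was also lost with a second quantile normalization (median 0.51, adjusted p = 0.0582) and with centred arrays (median 0.57, adjusted p = 0.0867).

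A further 5 lists passed with the preset correlation. Endothelium (median 0.39), mast cell and basophil (0.32) and stem and progenitor (0.25) transcripts had no member past over all genes or adjusted over the list alone, at adjusted p of 0.00406, 0.00537 and 0.0338, and adjusted p = 0.576, 0.539 and 0.534 with an estimated correlation. Without DX2 1 their medians were 0.24, 0.11 and 0.12 and none passed, and the stem and progenitor call was also lost without control 1 (0.16) or DX2 3 (0.19). The stem and progenitor median was 0.38 without DX2 2, and the endothelium median was 0.25 without DX2 3. Monocyte transcripts had a median of 0.31, with 0 over all genes and 2 adjusted over the list alone, Ms4a6c (0.74) and Treml4 (0.60), at adjusted p = 0.0435 and adjusted p = 0.493 with an estimated correlation, and were not past without control 1 (0.27), control 2 (0.24) or DX2 1 (0.09). Adipose transcripts, which whole spleen can carry from surrounding fat, had a median of -0.20 and none past over all genes or adjusted over the list alone, at adjusted p = 0.0108 and adjusted p = 0.493 with an estimated correlation, and were not past without control 1 (-0.12) or DX2 2 (-0.15). Their median was -0.13 with a second quantile normalization and -0.11 with centred arrays, and the list passed in both.

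In total 25 of 43 lists passed camera with the preset correlation, 20 higher and 5 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.377) or with the directional test fry (smallest adjusted p = 0.0900). The estimated correlation was 0.96 for the erythroid and MHC class II lists, 0.92 for megakaryocyte, 0.86 for neutrophil and 0.81 for T cell transcripts, far above the preset 0.01. It was 0.34 for the B cell list, 0.06 for amino acid response and 0.03 for red pulp macrophage transcripts. With a sex term 17 of the 25 still passed, and the tRNA synthetase complex, monocyte, neutrophil, megakaryocyte, stem and progenitor, endothelium, glycolysis and adipose lists did not, nor did these, the adipose list excepted, in the 4 male spleens. The neutrophil, monocyte and megakaryocyte lists were also not past without the dimmest 40% of genes, with array weights, with a second quantile normalization or with centred arrays. The same held for the mast cell, stem and progenitor and adipose lists without the dimmest 40%, glycolysis with array weights, the tRNA synthetase complex with a second quantile normalization, and stem and progenitor with centred arrays. Of the 18 lists that did not pass, the largest medians were those of the senescence (0.29), TGF-beta (0.23), antioxidant NRF2 (0.17) and p53 (0.13) lists, followed by the WNT (0.09) and RAS-ERK (0.09) lists. Plasma cell (-0.10), germinal centre B cell (-0.13), dendritic cell (-0.10), NK and cytotoxic (-0.15), NF-kB (-0.10), circadian clock (-0.06), cytosolic ribosome (-0.04) and T helper cytokine (-0.02) transcripts had lower medians without passing. The regulatory T cell median was 0.03. Some of these passed in other fits with the preset correlation: the p53 list without DX2 1 (0.28), with a sex term and in the 4 male spleens (0.24 in both), TGF-beta without control 1 (0.30), antioxidant NRF2 with array weights (0.25) and without control 3 (0.21) or DX2 2 (0.39), the dendritic cell list with centred arrays (-0.01), and, without DX2 2, the NF-kB (-0.29), NK and cytotoxic (-0.37) and dendritic cell (-0.18) lists. For stroma and fibroblast transcripts the median (-0.03) and mean (-0.01) lay below 0 while camera's direction was upwards, for marginal zone macrophages the median was -0.02 and the mean 0.11, and for pancreas transcripts the median was -0.0004 and the mean 0.0061.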

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

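The sex term, the 4 male spleens alone and the test of all probe sets together were chosen after the result was seen. The count of 70 genes was 69 to 84 with a trend, a robust prior, a second quantile normalization, other probe set rules or every one-gene probe set. It was 1 with the replicate block, 125 (28 higher, 97 lower) without the dimmest 40%, 547 (219 higher, 328 lower) with array weights, 2 with centred arrays, 2 with the sex term, 0 in the 4 male spleens (smallest adjusted p 0.372, limma), 1 with all 41345 probe sets tested together (unnamed, several-gene and further ones per gene added), 46 with a log2 size of at least 1, 394 at an adjusted p under 0.1, and 1 to 372 without single arrays. The block, sex-term and male fits have fewer arrays or degrees of freedom, which lowers power. The count nevertheless rose to 372 without DX2 2, also a fit with fewer arrays, so this need not explain the falls. What caused the shifts was not tested. With the robust prior 68 of the 70 calls held, and Cr2 and Fcer2a lost theirs (adjusted p = 0.0596 and 0.0560, limma). The median absolute difference of the 70 genes, 1.10, was 1.18 in the male spleens, and named genes kept their sign in 407 of 407 alternatives. These values are not independent support, since the genes were picked on the same arrays. The naming rule, which asked for groups that do not overlap, fixed the sign in every fit that kept the values and probe sets. Same-numbered arrays did not deviate together (correlations -0.32, -0.14 and 0.07). With 3 arrays per group and controls of both sexes, this cannot exclude that the replicate numbers pair the samples. The list count stayed between 18 and 26 except at 0 with an estimated correlation and 0 with fry, the block called 25 lists, and 14 of 25 called lists held in all 17 alternatives to the fit. By camera's direction the neutrophil list reversed without DX2 1 (medians without single arrays -0.038 to 0.83), with the sex term (0.044) and in the male spleens (0.044), and the megakaryocyte list without DX2 1 (-0.12 to 0.94 without single arrays). These reversals follow from the DX2 1 and control 3 values, and for the rest the cause was not tested. The Aimp2 and Eif2ak1 probe set stayed short of the threshold throughout (0.19 to 0.38). No signal over background was used, so the floor of detection is unknown here.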

Other observations

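Beyond the named genes, which follow a fixed rule, the genes in this paragraph were chosen after their values were seen. Among the 62 genes that fell were the oxysterol receptor Gpr183 (-1.25), which guides B cells within follicles, the cannabinoid receptor Cnr2 (-1.06), the transcription factors Foxp1 (-1.12), Ets1 (-0.80) and Zbtb18 (-0.91), the NF-kB kinase Ikbkb (-0.86), Bin1 (-0.93), the kinase Lrrk2 (-1.26) and the diacylglycerol kinases Dgka (-1.10) and Dgkd (-0.75), at adjusted p between 0.0387 and 0.0456 (limma, Benjamini-Hochberg). Bank1, a B cell adaptor, was at -1.10 with an adjusted p of 0.0569 and did not pass. Of 545 small nucleolar RNA and microRNA genes 330 were lower and 215 higher (median -0.07), and 4 fell, including Snord85 (-0.92). The 16010 unnamed probe sets had a median difference of -0.10, and 1 of them passed, lower in DX2, when all 41345 were tested together.

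Of the tests below, that of Gdpd3's neighbours and the counts of splits were set before their results were seen, and the tests on sex, T cells, spread within the B cell list, erythroid transcripts and other cell types (3 comparisons, with that of 13 lists run last, after the others left the question open) were chosen after the result was seen. The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 70 genes against at most 1 in any other split (1 split as large, the real one). It gave 25 lists against 9 to 21 in the other splits (1 as large), the lists being counted with the preset correlation. Splits that mix the genotypes thus called many lists too, so a large count of lists was not particular to the real split.

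The fall of B cell transcripts was set against sex and against changes in cell makeup. With a sex term, which rests on control 3 as the one male control, the B cell score still differed by -1.52 (SE 0.35), against sex as the whole cause. The B cell score also fell further than the T cell score, by -0.97 (SE 0.26), which argues against other cells thinning all lymphocytes alike. The differences of the 13 members spread by 0.70 (SD), above the 0.504 that replicate error gives at its 95th percentile, so the measured falls were unequal. Unequal compression of probe sets could make falls from fewer B cells unequal too. The spread therefore cannot decide whether fewer B cells are the whole cause. Fewer B cells as part or all of the cause and a change among B cell types stay open and untested. So do unequal compression of probe sets and an effect of DX2 or rtTA within B cells.

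The cell cycle pattern may stem in part from erythroid cells. With the erythroid score as a covariate the cell cycle difference went from 0.91 (SE 0.34) to 0.45 (SE 0.13). Its 95% interval on 3 degrees of freedom was 0.05 to 0.86. The score is an imprecise stand-in for erythroid precursors, and adjusting for it can leave part of their effect in place. The remainder therefore cannot decide whether they are the whole source. With a sex term the cell cycle difference was 0.72 (SE 0.54), so sex and genotype cannot be told apart for this list. Fewer B cells would raise all other cell types by about as much. The 13 cell type lists outside the B lineage had a median score difference of 0.34 (SD 0.39 over the lists), below 0.91 by more than that SD and with 12 of 13 below it. That SD is over lists and not over arrays, so it leaves out the error of the cell cycle difference (SE 0.34). Across arrays the mean T cell, NK, stroma and endothelium score differed by -0.016 (SE 0.18). The cell cycle score exceeded that mean by 0.93 (SE 0.49), and the red pulp macrophage score exceeded it by 0.61 (SE 0.23, 95% bound 0.63). Neither excess has a 95% interval that excludes 0. These comparisons therefore cannot decide whether fewer B cells are part or all of the cause, and both stay open.

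Gdpd3 differed by more than any other gene that rose and stayed past the threshold in 16 of 17 alternatives, the exception being the 4 male spleens (difference 3.08, adjusted p = 0.372 with limma, against 6.19e-05 to 0.372 over all alternatives). With a sex term it differed by 3.08 (SE 0.14), against sex as the cause. The 10 measured neighbours on each side, by gene order in GRCm38.p6, had a median absolute difference of 0.12, at the 25.4th percentile of such windows. Of these 20 genes 0 passed the threshold and 1, Coro1a (-0.54), had an unadjusted p under 0.05 (limma). This argues against a shared shift of the neighbouring genes. A strain segment that changes only a few genes would not move this median, so it stays open. Other possible causes, none of them tested, are an insertion that acts on Gdpd3 alone and signal from transgene RNA on its probe set. A response to DX2 or to rtTA also stays open and untested.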
